A study of Mus musculus with 12 samples.

How the data were processed

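RNA from 12 liver samples, 3 in each of 4 groups, was sequenced. Per the labels' protocols the mice were male and 8 to 10 weeks old, and the HFHS diet was fed for 16 weeks. That age is shorter than the feeding time, so it cannot be the age of the HFHS mice at sampling. A feeding time was recorded for the HFHS groups only. Whether control and HFHS mice were of the same age at sampling is thus not known. The labels give polyadenylated RNA as the material and name a stranded kit and a further library kit for every sample, without their settings. Per the submitters' processing notes, cutadapt, FastQC, HISAT2, StringTie and edgeR were used with the mouse build mm10, with no versions or roles given. The deposited tables hold whole-number estimated counts per gene and per transcript, judged from their values to carry no normalization, and each gene count is the exact sum of its transcript counts. Such estimates can rest on transcript coverage, so reads shared by near-identical genes can be split between them. They were whole already, so rounding changed none. The authors also deposited values per gene and transcript that the counts and lengths showed to be FPKM. These were used only for Lpcat3, with tests on log2 of the value plus 0.1. The edgeR test had been planned for plain counts and was kept for these estimated counts. No row was without a gene name, and 0 columns of the tables were left without a sample. The deposited tables that repeat part of the full tables, and the authors' correlations between libraries, were not used. Of 55401 gene identifiers counted, 54815 had the same start and end in the reference annotation.

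Total counts per library ran from 34951150 to 59205759. Genes were kept with filterByExpr of edgeR, which left 15982, and libraries were scaled with TMM. All 12 libraries were fitted in 1 model with a term for each group, which left 8 residual degrees of freedom, and 5 comparisons were tested with the edgeR quasi-likelihood test with robust dispersions. Adjusted p is Benjamini-Hochberg over the tested genes, with calls at 0.05. CPM values are scaled by TMM, and a fold against a group at 0 counts is a lower bound set at 3 counts over the group, which covers counting error only. Gene lists were written down before the data were examined, 24 of gene groups and 14 of cell types, of which 36 had at least 5 measured genes. The adipocyte list (4 measured genes) and the exocrine pancreas list (2) were not tested. Lists were tested with camera of limma at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with the correlation estimated for each list.

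Genes named in the text were chosen by a rule written before the data were examined. It takes Lpcat3 and Sult1e1 in every comparison, and the 5 largest rises and 5 largest falls between groups. These must be called, have a mean CPM of at least 1 in the higher group, show no overlap of values and carry no clone or predicted name. It adds up to 4 genes of smallest p in each list described, called or not, and for the interaction the 5 called genes of smallest p. Members of near-identical families were marked as uncertain. Not every gene the rule takes is reported here. No 2 libraries of a group held the same counts (chi-square per gene of at least 83.27 against counting noise). Repeat preparations of 1 sample can also differ by that much, so this does not tell whether the libraries came from separate animals, and each was counted as labelled. Deviations from group means correlated above 0.1 in each of the 3 same-number pairs of the diet comparison in knockout livers (0.101 to 0.294), so the fit with the replicate number as a block is given beside its results where it changed them, a reading made after both fits had been seen. In the other comparisons between groups at least 1 pair lay below 0.1. This rule does not show that samples were paired, since LKO-NC replicate 3 and LKO-HFHS replicate 2, of unlike number, reached 0.111.

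The alternatives planned before the data were examined were RLE size factors, no scaling factor, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2, the 6 libraries compared alone, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, an estimated correlation, camera on ranks, genes of at least 5 CPM for correlations, and FPKM or summed transcript counts for Lpcat3, of which the latter equal the gene counts and test nothing. Those chosen after seeing the data were the ribosomal RNA share as a covariate, limma voom with sample quality weights, leaving out the 4 libraries numbered 1, leaving out the 2 libraries of lowest scaling factor, and removing ribosomal RNA and mitochondrial genes.

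The tests were run on simulated data, with counts of 15982 genes drawn from the means and depths of these libraries and 200 genes changed, 100 of them by 2-fold and 100 by 4-fold. The main test found 53% of the 4-fold and 3% of the 2-fold changes for the diet in floxed livers, 48% and 3% for the diet in knockout livers, 48% and 5% for the knockout on the control diet, 48% and 3% for the knockout on the HFHS diet, and 18% and 1% for the interaction. For the diet in floxed livers 4 of its 60 calls were false, against 36 of 123 for DESeq2 and 6 of 59 for limma voom with sample quality weights. With no gene changed, the main test made 0 calls in each comparison. Each gene was drawn independently, so the simulated libraries lack any variation shared across genes. False calls from such shared variation are therefore not measured. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.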

Results

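Gene expression was measured by RNA sequencing in the livers of male C57BL/6 mice that carried a floxed Lpcat3 gene (FLOX) or had lost it in the liver (LKO). Lpcat3 encodes a lysophospholipid acyltransferase that places polyunsaturated fatty acids into phospholipids. Mice of each genotype were fed a control diet (NC) or, for 16 weeks, a diet rich in fat and sugar that the labels abbreviate HFHS. The labels name sucrose as the sugar of this diet in 1 place and fructose in another. There were 4 groups of 3 libraries each, 12 in all. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical. Total counts per library ran from 34951150 to 59205759 over 55401 genes. Of these genes 15982 passed the filter on low counts and were tested.

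A single ribosomal RNA gene, CT010467.1 on chromosome 17, took between 5.82% and 32.7% of the counts of a library. Its mean share was 15.8% ± 14.7 (SD, n = 3) in FLOX-NC, 8.19% ± 2.06 (SD, n = 3) in LKO-NC, 22.3% ± 3.94 (SD, n = 3) in FLOX-HFHS and 16.1% ± 9.56 (SD, n = 3) in LKO-HFHS. The libraries numbered 1 lay at one end of the main axis within groups, which held 32.1% of the variance within groups, and FLOX-HFHS replicate 1 and FLOX-NC replicate 1 had the lowest scaling factors, 0.644 and 0.752.

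The first question was whether the targeted gene was lower in the libraries labelled as knockout. Lpcat3 (ENSMUSG00000004270, mm10 chromosome 6, 124663027 to 124704418, plus strand, a protein-coding gene) stood at 53.8 ± 6.99 CPM (SD, n = 3) in FLOX-NC and 36.6 ± 24.8 CPM (SD, n = 3) in LKO-NC. On the HFHS diet it stood at 76.3 ± 3.99 CPM (SD, n = 3) in FLOX and 26.7 ± 2.32 CPM (SD, n = 3) in LKO. The wide spread in LKO-NC came from the library labelled LKO-NC replicate 2, at 65.0 CPM, against 25.4 and 19.4 CPM in LKO-NC replicates 1 and 3 and 49.7 to 61.9 CPM in the floxed libraries on the same diet. Lpcat3 therefore went against the label of that library. Every direction given below for the knockout on the control diet, for the diet in knockout livers or for the interaction includes it. The labels do not say which exons were deleted, so reads from the rest of the gene may remain in a knockout. The log2 fold change of Lpcat3 by the knockout was -1.51 ± 0.35 (SE) on the HFHS diet, with an unadjusted p of 0.000948 and an adjusted p of 0.683, and -0.56 ± 0.35 (SE) on the control diet, with an adjusted p of 0.718 (edgeR quasi-likelihood, Benjamini-Hochberg over all tested genes). Over the alternatives that use counts, the adjusted p on the HFHS diet ran from 0.0395 in DESeq2, at a log2 fold change of -1.52, to 1 in edgeR fits that leave out 1 library. In the authors' FPKM, on log2 of the value plus 0.1, the change on the HFHS diet was smaller, -0.83, with an adjusted p of 0.469 (limma). On the control diet the log2 fold change of Lpcat3 was -1.26 without LKO-NC replicate 2, -0.35 without LKO-NC replicate 1 and -0.22 without LKO-NC replicate 3.

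Sult1e1 (ENSMUSG00000029272, mm10 chromosome 5, 87575969 to 87591594, minus strand), the estrogen sulfotransferase named with Lpcat3 in the title of the series, was low in every group. It stood at 0.136 ± 0.121 CPM (SD, n = 3) in FLOX-NC, 0.0703 ± 0.122 in LKO-NC, 1.64 ± 0.688 in FLOX-HFHS and 0.285 ± 0.147 in LKO-HFHS. Its log2 fold change by the HFHS diet in floxed livers was 3.61 ± 1.40 (SE) with an adjusted p of 0.198, and by the knockout on the HFHS diet -2.51 ± 1.31 (SE) with an adjusted p of 1 (edgeR quasi-likelihood, Benjamini-Hochberg). The diet effect on Sult1e1 in floxed livers had an adjusted p of 0.0401 in DESeq2 and 0.0453 in limma voom with sample quality weights.

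**Figure D1:**
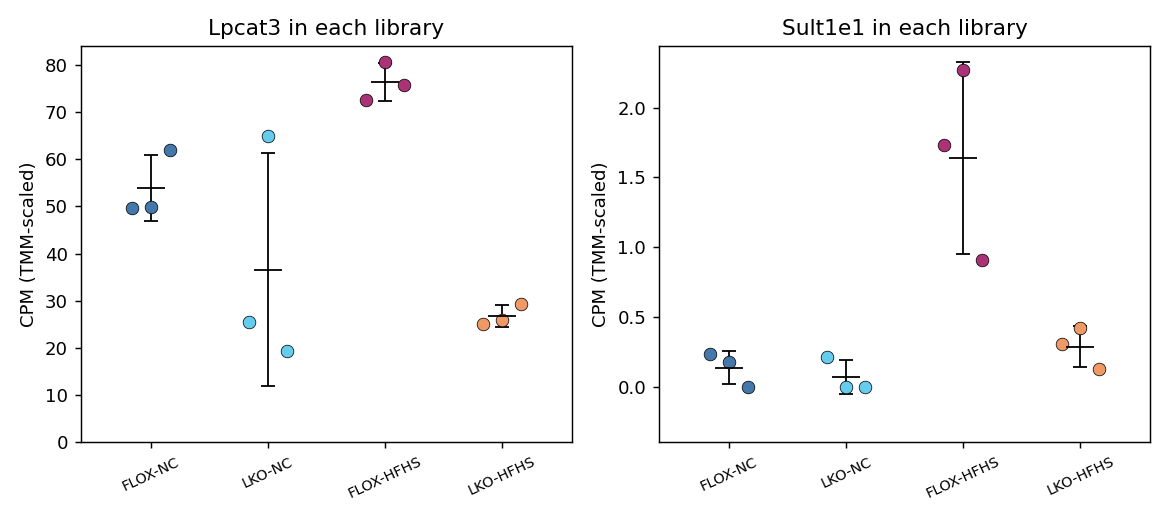
CPM, scaled by TMM, of Lpcat3 and Sult1e1 in each of the 12 libraries, with points ordered by replicate number and bars for the mean and SD of 3 libraries. The library labelled LKO-NC replicate 2 lies at 65.0 CPM of Lpcat3, while the LKO-HFHS libraries lie between 24.96 and 29.35 CPM and the FLOX-HFHS libraries between 72.6 and 80.6 CPM.

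The effect of the HFHS diet was first asked in floxed livers. Of 23 measured genes known to be expressed more in male than in female liver, 11 fell and 0 rose. Hsd3b5, a male-specific steroid dehydrogenase, changed by -7.06 ± 0.78 (log2, SE), from 163 ± 105 to 1.31 ± 1.29 CPM (SD, n = 3). Selenbp2 changed by -5.65 ± 0.62, Serpina1e by -5.48 ± 0.64 and Cyp4a12b by -4.53 ± 0.45 (log2, SE). Of 18 female-biased genes 6 rose and 1, Cyp2c69, fell. Cyp2b13, a cytochrome P450, was at 0 counts in FLOX-NC and was at least 353-fold higher on the HFHS diet, and Cyp2b9 rose by 5.44 ± 0.84, Cyp2a4 by 3.95 ± 0.72 and Ntrk2 by 3.89 ± 0.50 (log2, SE). The male-biased list had a camera adjusted p of 3.58e-15 and the female-biased list 0.00397, and both calls were lost with adjusted p = 0.177 with an estimated correlation. Adjusted over the list alone, 18 male-biased genes were lower and 0 higher, and 9 female-biased genes were higher and 3 lower.

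Lipid genes moved in the same livers. Of 22 measured genes of fatty acid synthesis and desaturation, 8 rose and 0 fell (12 and 0 adjusted over the list alone). Pklr, the liver pyruvate kinase, rose by 2.56 ± 0.25, Thrsp, a lipogenic regulator, by 2.83 ± 0.43, Acaca, acetyl-CoA carboxylase, by 2.34 ± 0.37 and Fasn, fatty acid synthase, by 1.92 ± 0.39 (log2, SE). The list median was 1.26, with a camera adjusted p of 4.01e-06, lost with adjusted p = 0.223 with an estimated correlation. Of 25 genes of lipid droplets and fatty acid uptake, 5 rose and 1 fell (5 and 3 adjusted over the list alone). Among them the fatty acid transporter Cd36 rose by 2.56 ± 0.31, and Cidec and Cidea, proteins of the lipid droplet surface, by 3.65 ± 0.48 and 4.43 ± 0.97 (log2, SE). The camera adjusted p of that list was 0.00732 (adjusted p = 0.231 with an estimated correlation). Of 19 lipoprotein genes 1 rose and 3 fell, with Apoa4 at 4.50 ± 0.60 and Apoa1 at -1.51 ± 0.29 (log2, SE).

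Of 24 genes of cholesterol synthesis and uptake, 23 had a negative log2 fold change and 2 fell, Nsdhl (-1.43 ± 0.24) and Hmgcs1 (-1.10 ± 0.24, log2, SE), and 15 were lower adjusted over the list alone. The median was -0.997, with a camera adjusted p of 1.04e-08 (adjusted p = 0.231 with an estimated correlation). Of 27 targets of the nuclear receptor PPAR alpha, 5 fell and 0 rose (9 and 2 adjusted over the list alone), with Acot1 at -2.12 ± 0.37, Cyp4a31 at -1.54 ± 0.27, Creb3l3 at -1.05 ± 0.20 and Acot8 at -0.83 ± 0.18 (log2, SE). Its camera adjusted p was 0.0146 (adjusted p = 0.186 with an estimated correlation), and the call ended without FLOX-NC replicate 3 (0.122) and without FLOX-HFHS replicate 1 (0.0611). In the bile acid list 3 of 22 genes fell and 1 rose (9 and 3 adjusted over the list alone), among them the transporter Slco1a1 at -4.91 ± 0.78 and Cyp7b1, an enzyme of the alternative bile acid pathway, at -2.82 ± 0.57 (log2, SE). Slco1a1 and Cyp7b1 stand in the male-biased list as well. The bile acid list had a camera adjusted p of 0.0199 (adjusted p = 0.223 with an estimated correlation), and the call ended without FLOX-NC replicate 3 (0.177) and without FLOX-HFHS replicate 1 (0.0504).

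Among markers of other liver cells in floxed livers, 5 of 12 Kupffer cell genes rose on the diet, with C1qa at 1.47 ± 0.26 (log2, SE), and the list had a median of 1.43 (log2) and a camera adjusted p of 1.86e-05 (adjusted p = 0.231 with an estimated correlation). Of 13 genes of monocyte-derived and lipid-associated macrophages, 0 passed the test over all genes by edgeR quasi-likelihood, with 9 at an unadjusted p under 0.05, while DESeq2 called 5 and voom 6, and 9 were higher adjusted over the list alone. The list had Trem2 at 4.48 ± 1.13 (log2, SE), called by DESeq2 (adjusted p 0.0315) and by voom (0.0135), and a camera adjusted p for the list of 4.87e-06 (adjusted p = 0.177 with an estimated correlation). Of 27 genes of the extracellular matrix 4 rose (12 adjusted over the list alone), among them Mmp12 by 5.84 ± 1.02 and Col4a1 by 1.25 ± 0.30 (log2, SE), with a camera adjusted p of 1.27e-08 (adjusted p = 0.231 with an estimated correlation). The 14 hepatocyte genes had a median of -0.38 (log2) and a camera adjusted p of 0.00563 (adjusted p = 0.365 with an estimated correlation), lost without FLOX-NC replicate 3 (0.195). Among single genes of other lists, Lcn2 rose by 5.09 ± 0.46, the glutathione transferase Gsta1 by 4.37 ± 0.38, the endothelial adhesion molecule Vcam1 by 2.19 ± 0.27 and the cyclin Ccnd1 by 1.95 ± 0.25, and G6pc, glucose-6-phosphatase, changed by -1.85 ± 0.25 (log2, SE).

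By fitted log2 fold change, the naming rule took as rises in floxed livers Cyp2b13, Pnpla5 (at least 140-fold higher), A4gnt (at least 134-fold), S100g (at least 79.6-fold) and Sprr1a (at least 65.9-fold), each at 0 counts in FLOX-NC, with bounds set at 3 counts over the group. The fitted value of a gene at 0 counts depends on the prior count, so these genes are not ranked against genes with counts. As falls it took Hsd3b5, Clec2h (-6.21 ± 0.81), Cyp2c69 (-5.90 ± 1.14), Selenbp2 and Serpina4-ps1 (-5.57 ± 1.10, log2, SE). In all, 464 of 15982 genes changed in floxed livers, 255 higher and 209 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and without a scaling factor 136 were higher and 163 lower. The count fell to 122 without FLOX-HFHS replicate 2, 142 without FLOX-HFHS replicate 3, 222 without FLOX-NC replicate 2 and 293 without LKO-HFHS replicate 3, and was 918 without the 4 libraries numbered 1. Serpina, Cyp2b, Cyp2c, Cyp4a, Mup and Acot genes belong to families of near-identical copies, so the split of reads among them is uncertain.

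In knockout livers the same question gave the following. Of 23 male-biased genes 19 fell and 0 rose (22 and 0 adjusted over the list alone), with Hsd3b5 at -9.78 ± 0.89, Serpina1e at -7.69 ± 0.71, Selenbp2 at -5.55 ± 0.61 and the fatty acid elongase Elovl3 at -3.87 ± 0.47 (log2, SE). Of 18 female-biased genes 9 rose and 0 fell (12 and 2 adjusted over the list alone), with Cyp2b9 at least 1533-fold higher, Cyp2b13 at least 170-fold higher, Ntrk2 at 7.48 ± 0.70 and Cyp2a4 at 5.30 ± 0.77 (log2, SE). Ntrk2 had 3 counts in LKO-NC, and its ratio of 210 had a 95% counting interval (exact binomial) of 71.5 to 1020. The camera adjusted p was 3.11e-27 for the male-biased and 4.96e-09 for the female-biased list, and both calls held with an estimated correlation (adjusted p = 0.0414 and adjusted p = 0.0121 with an estimated correlation). The estimated-correlation call of the male-biased list held in 2 of the 12 fits that each leave out 1 library, with a highest adjusted p of 0.0703 without LKO-NC replicate 3, and that of the female-biased list held in all 12. With the replicate number as a block both calls ended (adjusted p = 0.104 for the male-biased and adjusted p = 0.0526 for the female-biased list, with an estimated correlation).

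Of 13 genes of monocyte-derived and lipid-associated macrophages 7 rose in knockout livers (10 adjusted over the list alone). Gpnmb was at least 180-fold higher, the chemokine receptors Ccr2 and Cx3cr1 rose by 3.56 ± 0.65 and 3.35 ± 0.70, and the lectin Lgals3 by 3.19 ± 0.60 (log2, SE). Of 29 interferon response genes 7 rose (16 adjusted over the list alone), with Ifit2 at 2.74 ± 0.48, Usp18 at 2.41 ± 0.45 and Gbp3 at 2.17 ± 0.36 (log2, SE). Both lists held with an estimated correlation (adjusted p = 0.0347 for the macrophage list and adjusted p = 0.0145 for the interferon list, with an estimated correlation), after camera adjusted p values of 3.77e-09 and 4.96e-09. Over the 12 fits that each leave out 1 library, the estimated-correlation call held in 7 for the macrophage list (highest adjusted p 0.0625, without FLOX-NC replicate 2) and in 12 for the interferon list. With the replicate number as a block both calls ended (adjusted p = 0.0939 for the macrophage list and adjusted p = 0.101 for the interferon list, with an estimated correlation), and with the ribosomal RNA share as a covariate too (adjusted p = 0.0789 and adjusted p = 0.0735 with an estimated correlation). Of 27 matrix genes 12 rose (21 adjusted over the list alone), with Col6a3 at 2.57 ± 0.45 and Mmp12 at 6.15 ± 1.002 (log2, SE), and a camera adjusted p of 1.26e-11 (adjusted p = 0.122 with an estimated correlation). Of 14 hepatocyte genes 3 fell, among them Serpina1c at -2.14 ± 0.33, and the list had a median of -0.85 (log2) and a camera adjusted p of 3.85e-08 (adjusted p = 0.103 with an estimated correlation).

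Of 22 genes of fatty acid synthesis 9 rose and 0 fell in knockout livers (15 and 0 adjusted over the list alone), with Pklr at 2.21 ± 0.25, Thrsp at 3.13 ± 0.44, Acaca at 2.09 ± 0.37 and Aacs at 1.40 ± 0.24 (log2, SE), and a camera adjusted p of 1.02e-08 (adjusted p = 0.0995 with an estimated correlation). Cd36 rose by 1.97 ± 0.30, Cidec by 3.63 ± 0.47, Mogat1, an acyltransferase of triglyceride synthesis, by 2.59 ± 0.58 and Apoa4 by 3.64 ± 0.58 (log2, SE). In the bile acid list 4 of 22 genes fell and 0 rose (8 and 1 adjusted over the list alone), among them Slco1a1 at -5.41 ± 0.80 and Cyp7b1 at -3.66 ± 0.60 (log2, SE), with a camera adjusted p of 0.000164 (adjusted p = 0.0569 with an estimated correlation). Of 25 genes of endoplasmic reticulum stress 3 fell, Sdf2l1 (-1.75 ± 0.36), Creld2 (-1.48 ± 0.31) and Herpud1 (-1.11 ± 0.27, log2, SE), with a camera adjusted p of 6.02e-05 (adjusted p = 0.183 with an estimated correlation). Of 24 immediate early and heat shock genes 4 fell, among them Hspa1b (-2.24 ± 0.30), Hspa1a (-3.08 ± 0.49) and Dnajb1 (-2.76 ± 0.54, log2, SE), with a camera adjusted p of 1.05e-05 (adjusted p = 0.32 with an estimated correlation). With the replicate number as a block the Dnajb1 call ended, at -2.56 (log2) and an adjusted p of 0.0586 (edgeR quasi-likelihood). The list of PPAR alpha targets had a camera p of 0.557 before adjustment, with 2 of 27 genes higher, Pdk4 by 1.79 ± 0.43 and Acot3 by 2.28 ± 0.57 (log2, SE).

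In knockout livers the naming rule took as rises, by the same fitted values, Cyp2b9, Gpnmb, Cyp2b13, Sprr1a (at least 114-fold) and Pnpla5 (at least 111-fold), each at 0 counts in LKO-NC. These bounds do not order the genes against those with counts, such as Ntrk2. As falls it took Capn8 (at least 207-fold lower), Hsd3b5, Mup7 (-8.35 ± 1.32), Serpina1e and Mup-ps17 (-6.90 ± 1.18, log2, SE). Capn8 was at 0 counts in LKO-HFHS, and with the replicate number as a block its call ended (edgeR quasi-likelihood, adjusted p 0.102). In all, 599 genes changed, 359 higher and 240 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), against 410 higher and 99 lower without a scaling factor. The count fell to 350, 269 and 395 without LKO-NC replicates 1, 2 and 3, and to 305, 370 and 220 without LKO-HFHS replicates 1, 2 and 3, and was 1052 without the 2 libraries of lowest scaling factor and 1118 with the replicate number as a block.

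Diet effects in the 2 genotypes, which share no library, were compared across genes, which are not independent replicates. The log2 fold changes had a Pearson r of 0.475 and a Spearman rho of 0.478 over 15982 genes. Of the genes called, 152 were higher in both genotypes, where independent lists would share 5.73, and 101 were lower in both, where they would share 3.14, with 0 called in opposite directions. Of the 464 genes called in floxed livers 450, or 97%, had the same sign in knockout livers, and of the 599 called in knockout livers 580, or 96.8%, had the same sign in floxed livers.

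**Figure D2:**
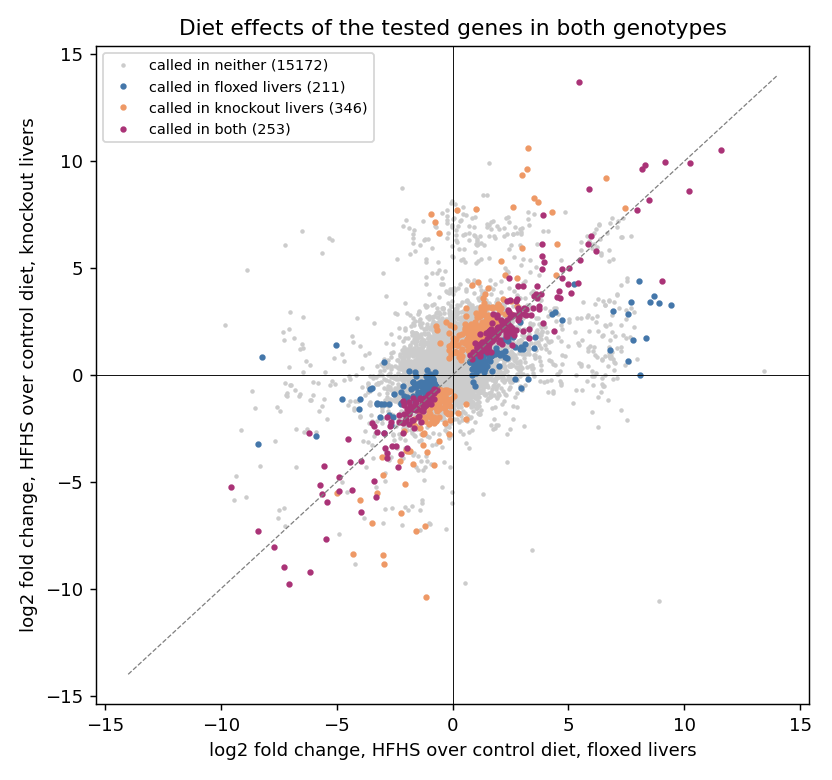
Log2 fold change of each tested gene by the HFHS diet in floxed livers (horizontal axis) and knockout livers (vertical axis), coloured by whether it was called in either, with a dashed line of equal change. The 253 genes called in both lie along the line in the upper right and lower left, at a Pearson r of 0.475 over all 15982 genes.

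The effect of the knockout on the control diet was asked next. The edgeR quasi-likelihood test called 0 of 15982 genes, with 1128 at an unadjusted p under 0.05 where 799 were expected by chance. DESeq2 called 72 genes and limma voom with sample quality weights 1. Among the lists, 21 of 24 immediate early and heat shock genes had a positive log2 fold change, with a median of 1.06, and 10 were higher adjusted over the list alone. Hspa1b stood at 108 ± 32.1 CPM in LKO-NC and 27.2 ± 8.02 CPM in FLOX-NC (SD, n = 3), a log2 fold change of 1.99 ± 0.30 (SE), and the small heat shock protein gene Hspb1 had 2.45 ± 0.39 (log2, SE). Their adjusted p values were 0.143 and 0.144 (edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 5 genes of the list, among them Hspa1b and Hspb1, and voom called 0. The list had a camera adjusted p of 3.27e-07 (adjusted p = 0.47 with an estimated correlation). Of 25 genes of endoplasmic reticulum stress 22 were positive, with Dnajb9 at 1.32 ± 0.37 (log2, SE) and a camera adjusted p of 1.25e-06 (adjusted p = 0.282 with an estimated correlation).

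The antioxidant list (20 of 22 genes positive, median 0.52, camera adjusted p 1.79e-05), the respiratory chain (28 of 29 positive, median 0.31, camera adjusted p 1.79e-05) and mitochondrial fatty acid oxidation (22 of 22 positive, median 0.29, camera adjusted p 0.000468) were called by camera with positive medians. With an estimated correlation they had adjusted p = 0.419, adjusted p = 0.582 and adjusted p = 0.546, respectively. The respiratory chain call ended without FLOX-NC replicate 1 (0.217), the library with the highest ribosomal RNA share. Interferon response genes were negative in 25 of 29 cases, with Ifit1 at -1.29 ± 0.43 (log2, SE) and a camera adjusted p of 0.000468, and the 9 genes of B and plasma cells were all negative, with a median of -1.25 and a camera adjusted p of 0.00367 (adjusted p = 0.282 with an estimated correlation for both). Lipid droplet genes were positive in 18 of 25 cases (median 0.36, camera adjusted p 0.00219) and PPAR alpha targets in 18 of 27 (median 0.29, camera adjusted p 0.00815), with adjusted p = 0.282 with an estimated correlation for both. Male-biased genes were positive in 20 of 23 cases (camera adjusted p 0.00381, adjusted p = 0.635 with an estimated correlation). The PPAR alpha call ended without FLOX-NC replicate 2 (0.0925) or LKO-NC replicate 2 (0.0927), and the male-biased call without FLOX-NC replicate 1 (0.436) or LKO-NC replicate 2 (0.143). Of 36 tested lists 13 were called and 0 held with an estimated correlation. The library labelled LKO-NC replicate 2 enters each of these values.

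For 3 lists of cell types and matrix called by camera in the same comparison, edgeR quasi-likelihood, DESeq2 and voom each called 0 genes, with 1 hepatocyte, 0 stellate cell and 2 matrix genes at an unadjusted p under 0.05. Hepatocyte genes were positive in 13 of 14 cases (median 0.32, camera adjusted p 0.00526), stellate cell genes negative in 12 of 13 (median -0.42, camera adjusted p 0.0095) and matrix genes negative in 22 of 27 (median -0.45, camera adjusted p 0.0237). With an estimated correlation they had adjusted p = 0.546, adjusted p = 0.401 and adjusted p = 0.719. Leaving out 1 library ended the hepatocyte call without FLOX-NC replicate 1 (0.362) or LKO-NC replicate 2 (0.0941). The stellate and matrix calls ended without FLOX-NC replicate 2 (0.0555 and 0.84), LKO-NC replicate 1 (0.0552 and 0.113) or LKO-NC replicate 2 (0.1 and 0.56).

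The PPAR alpha list lay higher in the knockout on the HFHS diet. Of its 27 measured genes 24 had a positive log2 fold change, the median was 0.48, and 6 were higher adjusted over the list alone. Over all genes 0 passed by edgeR quasi-likelihood, with 10 at an unadjusted p under 0.05, while DESeq2 called 3 (Acot1, Cyp4a14 and Acot3) and voom 5 (Acot1, Acot3, Pex11a, Cyp4a31 and Cyp4a14). Acot1, an acyl-CoA thioesterase, stood at 8.89 ± 3.48 CPM in LKO-HFHS and 2.14 ± 0.975 CPM in FLOX-HFHS (SD, n = 3), a log2 fold change of 2.03 ± 0.36 (SE). Acot3 had 2.58 ± 0.58, Cyp4a14, a fatty acid omega-hydroxylase, 1.95 ± 0.38 and Cyp4a31 1.07 ± 0.27 (log2, SE). The list had a camera adjusted p of 5.56e-12 and held with an estimated correlation (adjusted p = 0.00415 with an estimated correlation), and it held so in each of the 12 fits that leave out 1 library. With the ribosomal RNA share as a covariate it had adjusted p = 0.124 with an estimated correlation, without the 4 libraries numbered 1 adjusted p = 0.368 with an estimated correlation, and without the 2 libraries of lowest scaling factor adjusted p = 0.175 with an estimated correlation. With the replicate number as a block it had adjusted p = 0.0795 with an estimated correlation. In all the call held in 13 of 17 alternatives, and 12 of those 13 were the fits that leave out 1 library. Fits that leave out a control-diet library keep every library compared here, so they bear mainly on the estimated spread.

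Mitochondrial fatty acid oxidation genes were positive in 21 of 22 cases, with Acot2 at 1.09 ± 0.26 and the carnitine transferase Cpt1a at 0.89 ± 0.24 (log2, SE), and a camera adjusted p of 4.62e-05 (adjusted p = 0.69 with an estimated correlation). Lipid droplet genes were positive in 21 of 25 cases, with Cidec at 1.96 ± 0.43 and Pnpla2, adipose triglyceride lipase, at 0.87 ± 0.20 (log2, SE), and a camera adjusted p of 0.000744 (adjusted p = 0.319 with an estimated correlation). Female-biased genes were positive in 13 of 18 cases with a median of 0.98 and a camera adjusted p of 0.000146 (adjusted p = 0.0564 with an estimated correlation). Acot3 and Cyp4a14 stand in this list as well as in the PPAR alpha list. Acute phase genes were negative in 19 of 24 cases, with Saa3 at -1.35 ± 0.39 and the haem carrier Hpx at -0.72 ± 0.27 (log2, SE), and a camera adjusted p of 2.69e-05 (adjusted p = 0.63 with an estimated correlation). Cholangiocyte genes were positive in 9 of 10 cases (median 0.50, camera adjusted p 0.0084) and cell cycle genes in 16 of 24 (median 0.28, camera adjusted p 0.0215), with adjusted p = 0.63 and adjusted p = 0.765 with an estimated correlation. The cholangiocyte call ended without FLOX-HFHS replicate 1 (0.278) or 2 (0.133), and the cell cycle call without FLOX-HFHS replicate 1 (0.83), LKO-HFHS replicate 2 (0.107) or LKO-HFHS replicate 3 (0.0616). Cholesterol synthesis genes were positive in 20 of 24 cases (camera adjusted p 0.00395, adjusted p = 0.837 with an estimated correlation), a call that ended without FLOX-HFHS replicate 1 (0.18) or LKO-HFHS replicate 2 (0.56). Endoplasmic reticulum stress genes were negative in 20 of 25 cases and male-biased genes in 17 of 23 (camera adjusted p 0.00395 and 0.00127, adjusted p = 0.715 and adjusted p = 0.836 with an estimated correlation). The first of these calls ended without FLOX-HFHS replicate 3 (0.0696) or LKO-HFHS replicate 1 (0.324), and the second without FLOX-HFHS replicate 1 (0.0953). The median of all genes moved by 0.44 (log2) without a scaling factor, so these changes are relative to the bulk of genes, and the medians of the acute phase, endoplasmic reticulum stress and male-biased lists turned positive there.

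The count of genes changed by the knockout on the HFHS diet was 0 of 15982 by edgeR quasi-likelihood, with 520 genes at an unadjusted p under 0.05 where 799 were expected by chance. DESeq2 called 32 genes and limma voom with sample quality weights 78. Fads2, a fatty acid desaturase, had 1.56 ± 0.32, the phospholipid transfer protein gene Pltp 2.59 ± 0.57 and Cyp2u1 -2.05 ± 0.33 (log2, SE), and DESeq2 called all 3 of these genes. Log2 fold changes by the knockout on the 2 diets had a Pearson r of 0.0597 across genes.

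**Figure D3:**
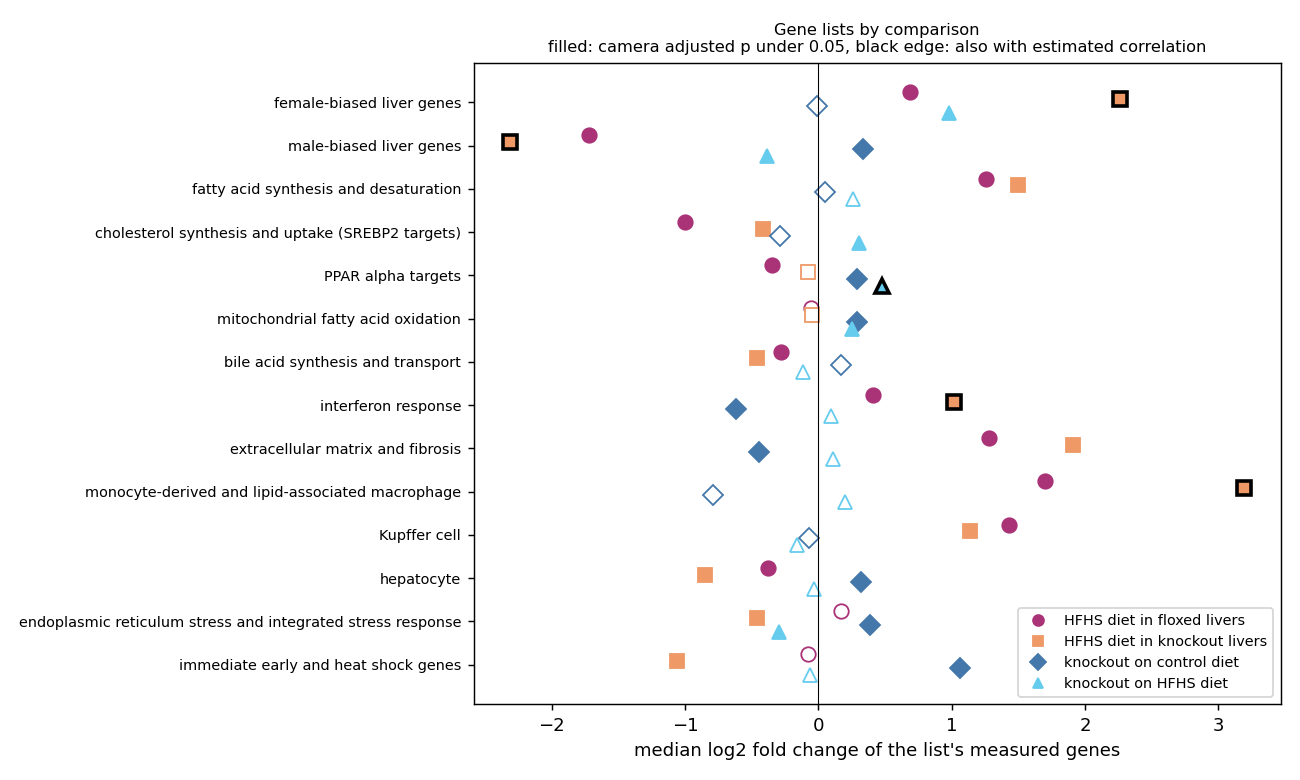
Median log2 fold change (horizontal axis) of the measured genes of 14 lists in the 4 comparisons between groups, filled where the camera adjusted p was under 0.05 and edged in black where the call also held with an estimated correlation. The PPAR alpha list lies at 0.48 for the knockout on the HFHS diet, and the male-biased list at -1.72 and -2.31 for the diet in floxed and knockout livers.

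**Figure D4:**
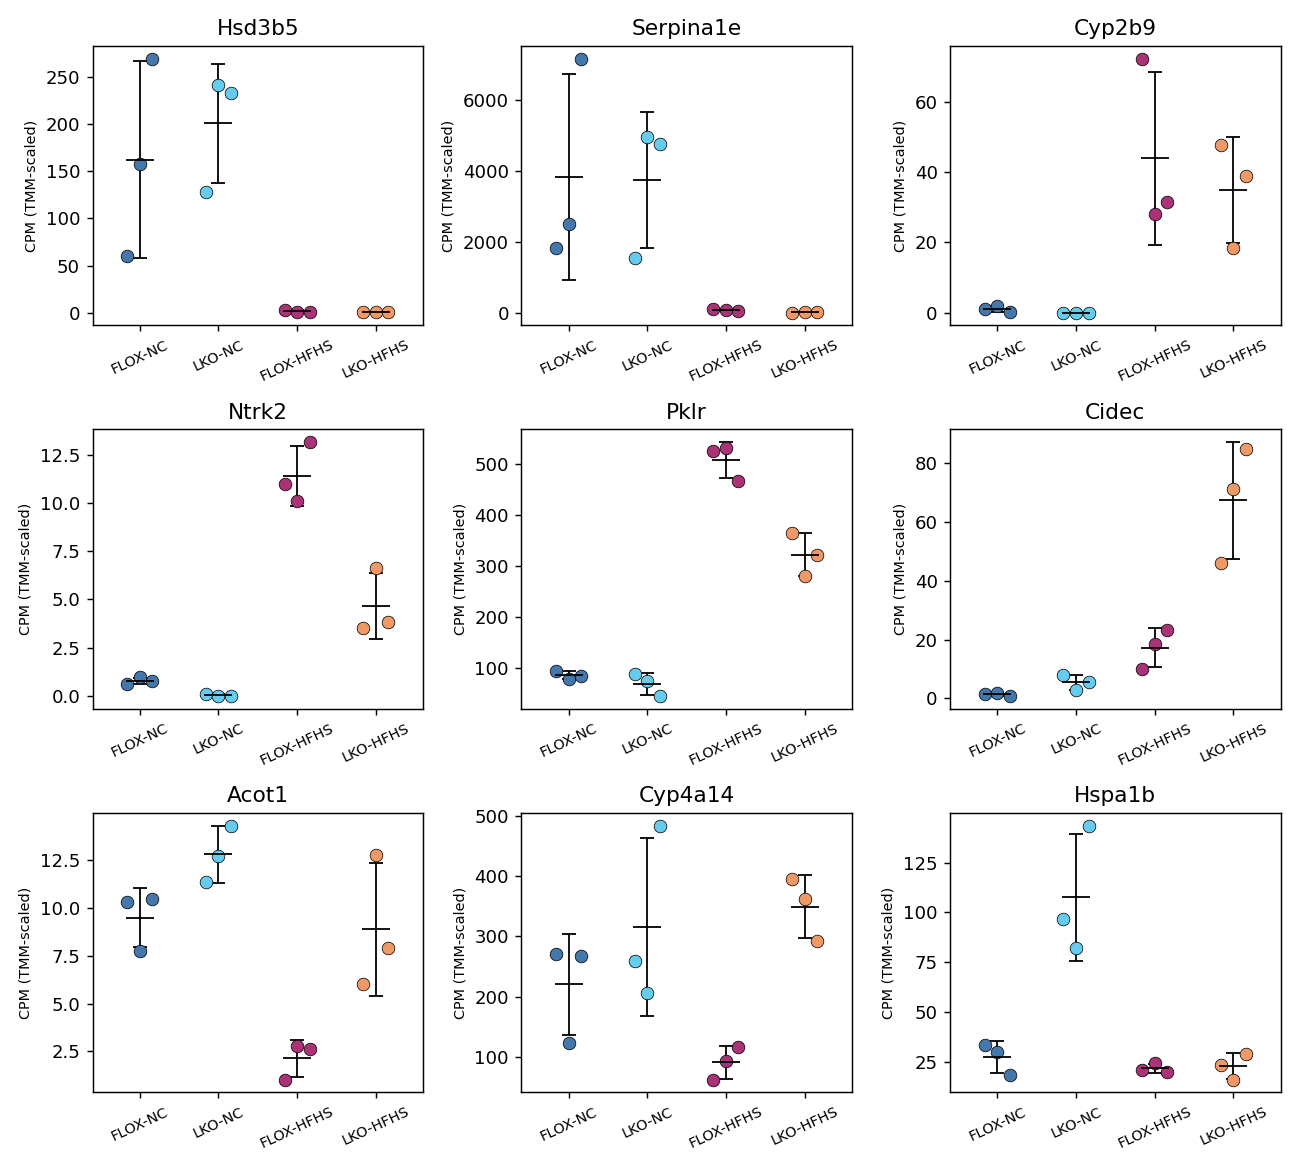
CPM, scaled by TMM, of 9 genes in each library, with points ordered by replicate number and bars for the mean and SD of 3 libraries. Acot1 lies at 2.14 CPM on average in FLOX-HFHS and at 8.89 CPM in LKO-HFHS, and Hspa1b at 108 CPM in LKO-NC and at 27.2 CPM in FLOX-NC.

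Whether the diet acted differently in the 2 genotypes was asked with the interaction term. The edgeR quasi-likelihood test called 0 of 15982 genes, with 782 at an unadjusted p under 0.05 where 799 were expected by chance. DESeq2 called 31 genes and limma voom with sample quality weights 0. Gsta1 had an interaction of -2.32 ± 0.48, Hspa1b of -1.91 ± 0.41, the interleukin 1 receptor gene Il1r1 of -1.48 ± 0.31 and Gclc, an enzyme of glutathione synthesis, of -1.19 ± 0.27 (log2, SE), each with an adjusted p of 0.758 (edgeR quasi-likelihood, Benjamini-Hochberg). Each of these genes was among those called by DESeq2. Lpcat3 had -0.96 ± 0.49 and Sult1e1 -1.57 ± 1.95 (log2, SE), with adjusted p of 0.955 and 0.958 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 36 lists 16 were called by camera and 0 held with an estimated correlation, and 8 were called without the 4 libraries numbered 1.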

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

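The tests on hepatocyte share, and those that use the ribosomal RNA covariate or leave out the libraries numbered 1, were chosen only after the results were seen. A difference between genotypes in the effect of the diet, tested by the interaction term, drew attention to 16 gene lists, none of which held with an estimated correlation. Over the fits that each leave out 1 library, 9 of the 16 calls at the preset correlation were lost at least once. Endoplasmic reticulum stress genes had a median interaction of -0.68 (log2, negative in 23 of 25 genes, camera adjusted p 1.62e-08), with Hyou1 at -1.29 ± 0.38 and Sdf2l1 at -1.65 ± 0.51 (SE). Immediate early and heat shock genes had -1.13 (23 of 24 negative, 5.69e-06), antioxidant genes -0.51 (18 of 22, 1.04e-05), acute phase genes -0.45 (20 of 24, 2.08e-05) and the respiratory chain -0.32 (28 of 29, 0.000403). Male-biased genes had -0.78 (20 of 23 negative, 6.5e-06) and female-biased genes 1.38 (15 of 18 positive, 7.43e-06), the list closest to holding (adjusted p = 0.0511 with an estimated correlation). Interferon genes had 0.65 (25 of 29 positive, 0.000809), cholesterol synthesis 0.59 (21 of 24, 0.00139), PPAR alpha targets 0.23 (17 of 27, 0.0219) and inflammatory genes 0.62 (18 of 25, 0.0309). Hepatocyte genes had -0.38 (12 of 14 negative, 0.00275), and cell cycle genes 1.01 (18 of 24 positive, 0.0185). Genes of lipid-associated macrophages had 0.71 (11 of 13 positive, 0.0273), cholangiocytes 1.18 (9 of 10, 0.031) and B and plasma cells 0.85 (9 of 9, 0.0349). Without a scaling factor the median interactions of the respiratory chain and hepatocyte lists turned positive. Immediate early and heat shock genes had a median of 1.06 for the knockout on the control diet and -1.06 for the diet in knockout livers. Their median was -0.06 for the knockout on the HFHS diet and -0.08 for the diet in floxed livers (log2). Their interaction thus rests on LKO-NC, which stood apart from the other groups and includes the library labelled LKO-NC replicate 2. Of 100 drawn splits of the genotype labels within diets, 10 called as many lists as the real one (16, highest other 18), so chance cannot be excluded. For genes the real count was 0, which 100 of 100 splits reach by construction, so their number says nothing. A single other split called 3304 genes, with FLOX-NC replicates 1 and 2 and LKO-NC replicate 1 set against the rest of the control diet and FLOX-HFHS replicate 2 and LKO-HFHS replicates 2 and 3 against the rest of the HFHS diet. No further split called more than 1. This points to a structure of the samples across the groups. The same split sorted the libraries by the share of counts from nuclear protein-coding genes. On the control diet the share was at most 64.1% in the libraries named and at least 75.1% in the rest. On the HFHS diet it was at least 59.1% in the libraries named and at most 55.6% in the rest. Whether this difference in composition made the calls was not tested.

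On the HFHS diet 23 of 23 male-biased genes had a negative and 15 of 18 female-biased genes a positive log2 fold change in knockout livers, and 22 of 23 and 13 of 18 did in floxed livers, where neither list held (adjusted p = 0.177 with an estimated correlation for both). Female animals among the HFHS libraries are argued against by the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, whose lowest sum in an HFHS library was 0.687 of the control-diet median. A lower share of hepatocytes would lower genes of both kinds alike, as far as hepatocytes make them. In knockout livers a female-biased median of 2.26 ± 0.968 argues against it (log2, bootstrap SE over genes). In floxed livers a male-biased median that differed by -1.34 ± 0.56 from the hepatocyte median does so too, while the female-biased median of 0.69 ± 0.747 excludes nothing. Both arguments are weak, because these SEs take genes as independent and hold no spread between libraries. The male-biased list had an estimated correlation of 0.411 between genes. The library axis as the whole cause is argued against, for male-biased genes only, by the share of calls kept in the less favourable of the fits with the ribosomal RNA covariate and without the libraries numbered 1 (0.842 of 19 in knockout and 0.909 of 11 in floxed livers) and by knockout medians of -2.16 ± 0.343 and -2.60 ± 0.395 against -2.31 ± 0.425, but the call of that list with an estimated correlation ended in both fits (adjusted p 0.0789 and 0.137), with 7 and 4 residual degrees of freedom in place of 8, and held in 3 of 17 alternatives. Without the libraries numbered 1 the ribosomal RNA share still separated the diets in floxed livers. It was 8.74% and 5.91% in FLOX-NC and 18.1% and 22.9% in FLOX-HFHS. In floxed livers the argument against this share thus rests on the covariate fit alone. The genes counted as kept had also been called in these same libraries. A weaker male pattern of growth hormone signalling on the diet may be a biological explanation, which no measurement here tested.

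The PPAR alpha list was higher in the knockout on the HFHS diet. Reads shared within the Acot and Cyp4a families are argued against as the whole cause by the 19 other genes. These had a median of 0.40 (log2), with 16 positive, and an unadjusted p of 0.0148 (camera with an estimated correlation). That p was not adjusted over the lists, so it does not show that the call stands without these families. That 1 library decides the list is argued against by a lowest median of 0.378 over the 6 fits that each leave out 1 HFHS library. The highest p with an estimated correlation over the fits with the ribosomal RNA covariate and without the libraries numbered 1 was 0.0297, but after adjustment over 36 lists both calls ended (0.124 and 0.368), as did that without the 2 libraries of lowest scaling factor (0.175): the median went from 0.475 ± 0.101 (log2, bootstrap SE) to 0.32 ± 0.147 with the covariate, a smaller effect, and to 0.509 ± 0.101 on 8 libraries, with 4 residual degrees of freedom in place of 8. With the replicate number as a block the call ended too (camera adjusted p 0.0795 with an estimated correlation), at a median of 0.474. A rise of PPAR alpha activity in livers without Lpcat3 may be a biological explanation only as a hypothesis, found and tested on the same libraries, since the adjusted call was not kept in these fits.

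Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes as the real split were called by 1 of 10 splits for the diet in floxed livers (464, highest other 1) and 1 of 10 in knockout livers (599, highest other 0). For the knockout 10 of 10 splits on the control diet (0, highest other 1) and 10 of 10 on the HFHS diet (0, highest other 0) did so, which a real count of 0 fixes in advance. As many lists as the real split were called by 1 of 10 splits for the diet in floxed livers (23, highest other 20), 1 of 10 in knockout livers (24, highest other 23), 3 of 10 for the knockout on the control diet (13, highest other 17) and 4 of 10 on the HFHS diet (10, highest other 13). The lists called at the preset correlation were thus close in number to those of the highest other split, or fewer.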

How the results depend on the processing

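The covariate, voom, left-out libraries numbered 1 or of lowest scaling factor, and removed ribosomal RNA and mitochondrial genes were tests chosen only after the results were seen. The main counts of changed genes, 464 and 599 for the diet in floxed and knockout livers and 0 for both knockout comparisons and the interaction, gave 1279, 1539, 72, 32 and 31 by DESeq2, which made more false calls on simulated data. Voom gave 3015 and 2284 for the diet, 1 (Ugt1a6b) and 78 for the knockout on the control and HFHS diets, and 0 for the interaction. The diet count in floxed livers was 299 without a scaling factor, 111 in the 6 libraries alone, 2040 with the ribosomal RNA covariate and 918 without the libraries numbered 1, and the count in knockout livers 1052 without the 2 libraries of lowest scaling factor. Without a filter the knockout on the control diet gave 2 genes (Ntrk2, Hspa1b), and without the libraries numbered 1 it gave 4 (Rdh9, Klf10, Ythdf3, Ntrk2) and the interaction 2 (Rdh9, Klf10), genes named after their values were seen. Without a scaling factor the knockout on the HFHS diet gave 1 (Socs2). With the replicate number as a block the 5 counts were 1257, 1118, 1 (Hspb1), 5 (Zfp992, Gm43410, Gm4956, Acot1, Cyp2u1) and 0, and the PPAR alpha call with an estimated correlation on the HFHS diet ended (adjusted p 0.0795), as did all 4 such list calls for the diet in knockout livers, where Capn8, Dnajb1 and Mki67 lost their calls and no other named gene changed its call. Of 18 pairs of libraries with the same number 13 correlated above 0.1, among them all 6 of number 1 (0.233 to 0.357), and 6 of 12 libraries matched best with their own number. As not every pair did, the numbers were treated as pairing the samples only for the diet in knockout livers. Whether they do so there is not shown. LKO-NC replicate 3 correlated at 0.111 with LKO-HFHS replicate 2, of unlike number, and at 0.101 with LKO-HFHS replicate 3. The causes were not tested. With an estimated correlation, lists called went from 23, 24, 13, 10 and 16 to 0, 4, 0, 1 and 0. Interaction lists fell to 8 both without the libraries numbered 1 and without the 2 of lowest scaling factor.

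Leaving out each library in turn, the counts ran from 122 to 535 and from 220 to 887 for the diet in floxed and knockout livers, 0 to 2 and 0 to 0 for the knockout on the control and HFHS diets, and 0 to 1 for the interaction. The knockout on the control diet gave Rbm42 and Ugt1a6b without FLOX-NC replicate 3, and Ythdf3 and Ntrk2 without LKO-NC replicate 1. The interaction gave Rbm42 without FLOX-NC replicate 3, and its lists ran from 9 (without FLOX-HFHS replicate 1) to 18, with 10 without LKO-NC replicate 1. The PPAR alpha call with an estimated correlation on the HFHS diet held in 13 of 17 alternatives (highest adjusted p 0.368), and 12 of those 13 were left-out-library fits. For the diet in knockout livers such calls held in 16 of 17 for the female-biased list (highest 0.0526), 15 for interferon (0.101), 8 for the macrophage list (0.202) and 3 for the male-biased list (0.137). Among the left-out-library fits, those without a library of a group not compared keep every library compared and bear mainly on the estimated spread. The r of the diet effects ran from 0.371 to 0.467 and was 0.636 over genes of at least 5 CPM. The r of the knockout effects ran from -0.0128 to 0.15, below 0 without FLOX-HFHS replicate 1 (-0.0128) and without FLOX-NC replicate 1 (-0.00085). Of 51 called genes named for floxed livers 24 kept their call in each setting and 22 lost it in at least 1 left-out-library fit, and of 53 for knockout livers 36 and 15. Over the 25 settings, no named gene changed direction where it was called in the main test or in the setting. Changes of direction of genes called in neither were not counted. Lpcat3 in FPKM had -0.51 on the control and -0.83 on the HFHS diet (log2 of the value plus 0.1). Without a scaling factor the median of all genes moved by -0.07, 0.27, 0.09, 0.44 and 0.35 (log2). At this depth and number of libraries the main test finds few 2-fold changes, so the counts of 0 set no limit on small effects.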

Other observations

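Of the tests in this part, those on a label swap and on the 20 labellings of the control-diet libraries were chosen only after the result was seen. Of 24 cell cycle genes 3 rose on the HFHS diet in knockout livers (11 adjusted over the list alone), among them Ccnd1 by 2.24 ± 0.26 and the proliferation marker Mki67 by 5.35 ± 1.27 (log2, SE), with a camera adjusted p of 4.33e-08 (adjusted p = 0.0791 with an estimated correlation). With the replicate number as a block the Mki67 call ended, at 5.42 (log2) and an adjusted p of 0.0632 (edgeR quasi-likelihood). Of 10 cholangiocyte genes 2 rose there, among them Spp1, osteopontin, by 2.58 ± 0.46, with a camera adjusted p of 6.36e-05 (adjusted p = 0.0823 with an estimated correlation). Of 13 stellate cell genes 3 rose, with a median of 1.11 (log2) and a camera adjusted p of 7.14e-05 (adjusted p = 0.0791 with an estimated correlation). Of 25 inflammatory genes 6 rose in knockout livers, among them Il1rn, an antagonist of interleukin 1, by 3.18 ± 0.35 and the chemokine Cxcl16 by 1.71 ± 0.30 (log2, SE), with a camera adjusted p of 9.5e-06 (adjusted p = 0.103 with an estimated correlation).

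Sulfotransferase genes went both ways on the HFHS diet. Sult1c2 rose by 2.65 ± 0.29 in floxed and 1.85 ± 0.29 in knockout livers, and Sult2a8 fell by 1.88 ± 0.35 and 2.31 ± 0.36 (log2, SE), while the list of 12 had a camera p of 0.675 and 0.516 before adjustment. Of 24 genes of glucose and fructose metabolism 6 rose and 1 fell in floxed livers, with a camera adjusted p of 0.00732 (adjusted p = 0.186 with an estimated correlation). Of 30 genes of phospholipid synthesis and remodelling 0 passed the test for the knockout on either diet by edgeR quasi-likelihood, DESeq2 or voom, with 1 at an unadjusted p under 0.05 on each diet and a list camera p of 0.247 on the control diet and 0.914 on the HFHS diet before adjustment.

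Lpcat3 stood at the floxed level in the library labelled LKO-NC replicate 2. A swap with a FLOX-NC library is argued against in CPM scaled by TMM, where the lowest FLOX-NC value was 1.69 times the highest of the other 5 LKO libraries. In the authors' FPKM, however, FLOX-NC replicate 1, at 15.76, lay within the range of those LKO libraries, 11.75 to 22.81. FPKM is relative to the whole library and carries no TMM scaling. Ribosomal RNA took 32.65% of the counts of FLOX-NC replicate 1, and nuclear protein-coding genes 37.5%. In LKO-NC replicates 1 and 3 the protein-coding share was 61.49% and 75.14%. Such a composition lowers the FPKM of other genes, so the overlap does not decide whether that library was swapped. Reads from cells other than hepatocytes are argued against by their markers, since 1 of 7 lists of such cells was highest in this library among the LKO-NC libraries. A single wrong label or an animal without deletion may still be the explanation. LKO-NC replicate 2 had its highest correlation of log2 CPM with FLOX-NC replicate 3 (0.960), against 0.952 and 0.943 with LKO-NC replicates 3 and 1. With FLOX-NC replicates 1 and 2 it had 0.8905 and 0.9231. FLOX-NC replicate 3 also correlated more with LKO-NC replicate 3 (0.9568) than with FLOX-NC replicate 2 (0.9293). Closeness between libraries thus does not tell the genotype here. LKO-NC replicate 2 was projected on the knockout effect of the HFHS diet, over 519 genes with an unadjusted p under 0.05 there (edgeR quasi-likelihood). It lay at -0.0178, against 0.107 and 0.0727 for the other LKO-NC libraries. FLOX-NC replicates 1, 2 and 3, each set against the other 2, lay at 0.0265, -0.0501 and 0.0235. These values cannot be told apart from chance, because 3 of those 20 labellings projected as high as the real one. The real labelling itself counts this library as a knockout. In the comparison used, 520 genes had such a p where 799 were expected by chance.

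Across genes, 1 of 100 drawn splits of the diet labels within genotypes, the real one, gave an r of the diet effects as far from 0 as 0.475 (highest other 0.371). Chance is thus unlikely but not excluded, since 100 of 200 distinct splits were drawn and some are mirror images that only turn the sign of r. For the knockout effects 52 of 100 drawn splits gave an r as far from 0 as the real 0.0597 (farthest other -0.398), so chance cannot be excluded. Of the lists with too few measured genes to test, the adipocyte list had 1 of 4 genes higher on the HFHS diet in floxed livers and 0 in knockout livers by edgeR quasi-likelihood, where 1 had an unadjusted p under 0.05 and DESeq2 and voom called 1. The exocrine pancreas list had 0 of 2 called in either by edgeR, with 1 in floxed and 2 in knockout livers at an unadjusted p under 0.05, as many called by DESeq2, and 1 in each by voom.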
